A study of Malus domestica with 6 samples.

How the data were processed

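The data are leaf RNA sequencing libraries of 6 apple (Malus domestica) cultivars, 1 library per cultivar, made from total RNA extracted with a modified CTAB method and standard Illumina library chemistry per the labels' protocols. The deposited table holds read counts per gene symbol, not normalized, 1 column per library. HISAT2, a spliced read aligner, and Subread, the package that holds the featureCounts read counter, are named without versions or settings per the submitters' processing notes. The strand setting and the treatment of reads that match several loci are not given in the sources used here, so counts of near-identical family members, overlapping genes and antisense pairs are uncertain at the level of the single gene. The deposited annotation is the NCBI annotation of the MalDomGD1.0 assembly of the cultivar Golden Delicious, per the file headers, and its symbols match those of the counts: 57371 of 57387 symbols were found in it, and the other 16 were pooled tRNA symbols. Product names and 1-based coordinates were taken from that annotation, in which 54390 symbols had a product name and 17699 of these were uncharacterized. Reads from alleles or genes that a resistant cultivar carries and Golden Delicious lacks would be lost or counted on a relative.

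Groups were taken from the scab resistance label: Florina, Mahraji and Prima formed the resistant group, and Vista Bella, Ambri and Red Delicious the susceptible group. Each cultivar stood for 1 replicate, so p-values measure the spread between single libraries of different cultivars, in which genotype, leaf and handling are not separated. The replicate numbers 1 to 3 follow accession order within a group and pair nothing. No sequencing batch or date is labelled. No library was a duplicate of another: the log2 CPM correlation of library pairs ran from 0.759 to 0.871.

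Library totals ran from 12327849 to 18437943 counts, and at least 99.1% of each library's counts lay in the 28915 genes kept by edgeR's filterByExpr, with a least count of 10 and a least total of 15. Ribosomal RNA genes took at most 0.0939% of a library. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, estimateDisp, robust glmQLFit, glmQLFTest) and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are resistant minus susceptible, with standard errors, and CPM values of named genes are TMM-normalized. The common biological coefficient of variation was 0.609. DESeq2 1.42.0 and limma-voom (limma 3.58.1) were run as alternatives. DESeq2 gave no adjusted p for 24785 genes, which its independent filtering, outlier rule or lack of reads left out.

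Fixed before the data were examined were the groups, the tests, 26 gene lists defined by regular expressions on product names, the rule for named genes and the alternative settings. The lists cover NLR genes (all, TIR type and coiled-coil type), receptor-like proteins, LRR and other receptor-like kinases, pathogenesis-related proteins, WRKY factors, phenylpropanoid and flavonoid enzymes, biphenyl phytoalexin enzymes, salicylate, jasmonate, ethylene, oxidative and calcium genes, MLO, cell wall, cuticle and epidermis, vascular, guard cell, cell division, senescence, photosynthesis, clock, heat shock and ribosomal protein genes. Some lists overlap, since the TIR and coiled-coil types are parts of the NLR list. The 25 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists, and again with the correlation estimated from the data and with fry. Camera asks whether a list's genes lie higher or lower than all other genes, and fry whether they move one way on balance. For each list, single genes were also adjusted over the list alone.

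The rule for named genes took the 10 largest changes in each direction among genes past the threshold, and in each list the gene with the smallest unadjusted p in each direction. It also took up to 5 receptor genes per group that were detected in that group and not in the other. As no gene passed the threshold and no receptor gene was detected in a single group, the list members remained. Other genes named in the text were chosen after their values were seen, which is said beside them.

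Expressed NLR genes were counted per library at 1 CPM or more of the library total, and group means were compared by an exact two-sided permutation test over 20 arrangements, which allows no p below 0.1. A gene was called detected in one group when it reached 1 CPM in all 3 libraries of that group and stayed under 0.1 CPM in the other 3. Distances between libraries were Euclidean on log2 CPM (prior count 2) of the 500 most variable tested genes. For a gene with no read in a group, the floor was 3 counts over the group. Shares of a library's counts carry Wilson intervals at 95% confidence, which cover counting error and not differences between leaves.

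The edgeR step was tested on simulated counts with the real means and library sizes and 200 changed genes among 28915. Of 67 genes changed 4-fold it called 4, of 67 changed 16-fold 38, and of 66 changed 64-fold 58, with 6 unchanged genes called. The spread of each simulated gene was the dispersion that edgeR had fitted to it, which need not match the real spread. In the real fit LOC103444965, at a log2 fold change of 8.77, had an adjusted p of 0.282 (edgeR's quasi-likelihood test). The simulated shares thus cannot be read as the recovery in the real libraries. The set test found the shifted list and 0 of 100 unshifted lists. The simulated genes were drawn independently of each other, so this could not check false calls among genes that vary together. In the real libraries the estimated inter-gene correlation was 0.167 for the heat shock list and 0.197 for LRR receptor kinases. Alternatives covered the tool, the scaling, the low-count filter, the empirical Bayes step, the threshold, the 20 most abundant genes, the detection minimum, thinning of all libraries to the shallowest, list membership and leaving out each cultivar. Added after seeing the data were a fit without Vista Bella and Ambri, a fit with the mean log2 CPM of the heat shock list as a covariate, and the lists without members caught by accident. The GTF copy of the annotation was not used here.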

Results

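Leaves of 6 apple cultivars were compared to find genes that go with resistance to scab, the leaf and fruit disease caused by the fungus Venturia inaequalis. Per the labels, Florina, Mahraji and Prima were resistant and Vista Bella, Ambri and Red Delicious susceptible (n = 3 cultivars per group, 1 library each), and all leaves were taken at the stage labelled walnut. Florina and Prima are known carriers of the Vf scab resistance, a locus of receptor-like protein genes introgressed from a wild apple. Whether the leaves had met the fungus is not given in the sources used here. Total counts were 12327849 for Florina, 13020152 for Mahraji and 14357364 for Prima, and 18437943 for Vista Bella, 15377580 for Ambri and 14418634 for Red Delicious.

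Between resistant and susceptible leaves, heat shock genes as a group were lower, and genes for immune receptors as groups were higher, in the resistant cultivars, while no single gene passed the edgeR test over all genes. Camera gave adjusted p = 3.38e-47 for the heat shock list and 3.24e-10 for LRR receptor kinases, and adjusted p = 0.274 and 0.481 with an estimated correlation. LOC103444965, annotated as receptor-like protein 2 (MalDomGD1.0 chromosome 10, 6442379 to 6448003), a cell surface receptor type without a kinase domain, had 61.9 ± 26.8 CPM (SD, n = 3) in resistant and 0.128 ± 0.165 CPM in susceptible leaves, a log2 fold change of 8.77 (SE 0.917). LOC103428561, an LRR receptor-like kinase gene (chromosome 7, 107988 to 108699), had 33.1 ± 7.78 against 1.52 ± 0.559 CPM, a log2 fold change of 4.44 (SE 0.434). AP2D38 (chromosome 4, 2718191 to 2720478), a gene of the DREB2A type of transcription factor that switches on heat and drought genes, had 18.8 ± 3.67 against 157 ± 36.3 CPM, a log2 fold change of -3.06 (SE 0.339). It was chosen after its values were seen. The groups did not overlap for these genes, but edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave each of them an adjusted p = 0.282, the lowest among 28915 genes.

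No gene passed an adjusted p of 0.05 in edgeR, and 1689 genes (5.84%) had an unadjusted p under 0.05, of which 802 were higher and 887 lower in resistant leaves. DESeq2 called 380 genes, 121 higher and 259 lower, with 2874 at an unadjusted p under 0.05, and limma-voom called 0, with 1642. Among the DESeq2 calls were 70 heat shock genes and 23 genes of the receptor lists, and LOC103444965 had a DESeq2 adjusted p of 3.75e-20. All resistant libraries lay above all susceptible ones for 1767 genes and below them for 1590, which is 11.6% of tested genes where chance gives 10%. Scaling by library size alone moved the median log2 fold change of all genes from 0.04 to 0.28 and the split at an unadjusted p under 0.05 to 1289 higher and 532 lower. The count at an unadjusted p under 0.05 was 3135 without Red Delicious (lowest adjusted p = 0.0542 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 1108 without Ambri, and 750 with Red Delicious as the lone susceptible library.

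Heat shock genes, which encode chaperones and the factors that induce them, were lower in resistant leaves as a group in camera, with adjusted p = 3.38e-47, and with no call at an estimated correlation, where adjusted p = 0.274 with an estimated correlation. Of 165 tested members 128 had a negative log2 fold change, with a median of -1.89, and the 85 members at an unadjusted p under 0.05 were all lower. Adjusted over the list alone, 78 members fell (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), by 1.19 to 10.3 on the log2 scale, and 0 passed over all genes. In 71 of the 78 all resistant libraries lay below all susceptible ones, but the same comparison had picked the 78. Of all 165 tested members 76 lay so, and 3 lay the other way. LOC103417756, an HSP70-15-like chaperone gene (chromosome 1, 1191007 to 1209072), had 3.43 ± 0.246 CPM in resistant and 39.98 ± 23.7 CPM in susceptible leaves, a log2 fold change of -3.54 (SE 0.514, adjusted p = 0.0122 over the list alone by edgeR). LOC103409766 (chromosome 6, 2588654 to 2592907), for ClpB1, which pulls apart protein aggregates after heat, had 17.2 ± 9.69 against 1466 ± 1135 CPM. LOC103440772 (chromosome 8, 8171677 to 8173894), for an HSF30-like heat shock factor, had 5.21 ± 2.13 against 170.1 ± 159 CPM. Both were chosen after their values were seen. The opposite direction was led by LOC103420228, a BAG-type co-chaperone gene, at 21.8 ± 15.3 against 8.25 ± 4.77 CPM, with an adjusted p of 0.833 over all genes in edgeR after Benjamini-Hochberg adjustment.

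The susceptible libraries differed among themselves in these transcripts. The heat shock list took 13.7% of the counts of Vista Bella, 6.21% of Ambri and 2.23% of Red Delicious, against 0.487% of Florina, 0.863% of Mahraji and 0.742% of Prima. The Wilson intervals are narrow, for example 13.694 to 13.725% in Vista Bella and 0.48349 to 0.49126% in Florina. Without Vista Bella and Ambri, against Red Delicious as the lone susceptible library, the list had a median log2 fold change of -0.59. That fit was chosen after seeing the data, and its susceptible side has no replicate.

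**Figure D1:**
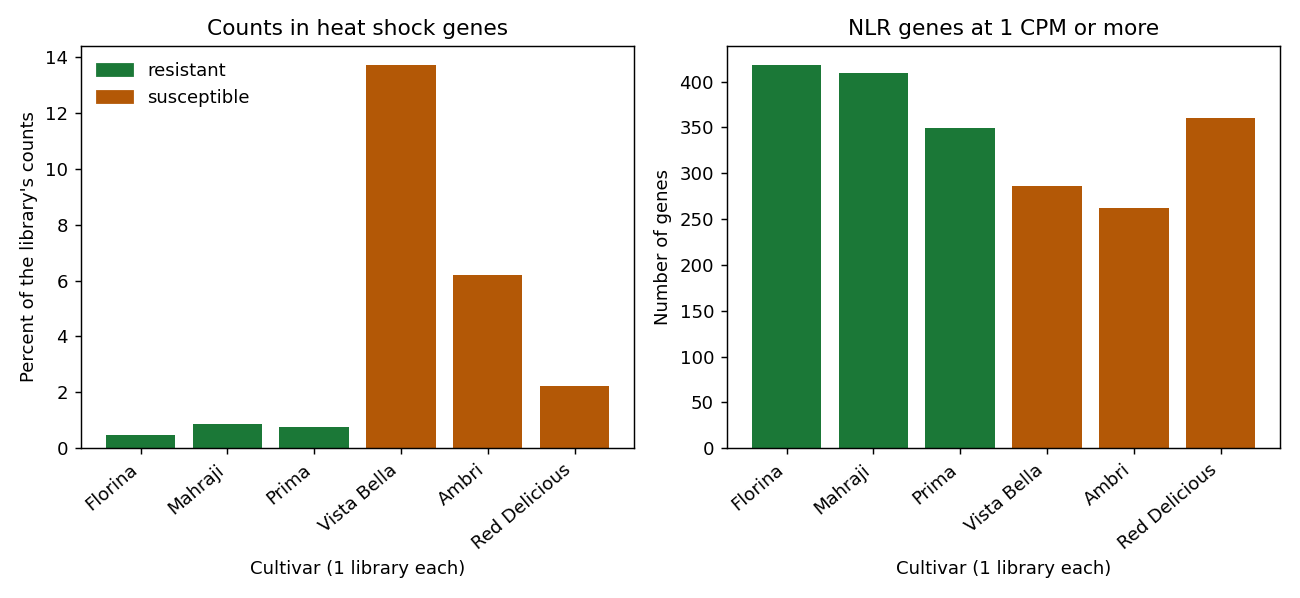
Bars give, per cultivar library, the percent of all counts in heat shock genes (left) and the number of NLR genes at 1 CPM or more (right), with resistant cultivars in green and susceptible ones in orange. Vista Bella reached 13.7% heat shock counts while each resistant library stayed below 0.9%, and Red Delicious, with 360 expressed NLR genes, lay between Prima with 349 and Mahraji with 409.

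Cell surface receptor genes were higher in resistant leaves as groups in camera, with adjusted p of 6.80e-06 or lower, and with no call at an estimated correlation, where adjusted p was 0.472 or higher. Of 25 tested receptor-like protein genes 20 had a positive log2 fold change (median 0.82), as did 171 of 226 LRR receptor-like kinase genes (median 0.58) and 86 of 107 genes of a list of wall-associated, lectin, cysteine-rich and LEAF RUST 10-type receptor kinases and an S-locus glycoprotein (median 0.66). Adjusted over the list alone, 4 receptor-like protein genes and 3 LRR kinase genes rose and 0 of the other kinases, against 0 over all genes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 were 5, 25 and 3 genes, all higher, and DESeq2 called 4 receptor-like protein genes higher, 8 LRR kinase genes higher and 1 lower, and 0 of the other kinases. The receptor-like protein genes were LOC103444965 at an adjusted p of 0.000789 over the list alone by edgeR, LOC103450293, LOC103430948 and LOC103426229. The LRR kinase genes were LOC103428561, LOC103440048 and LOC103413690. Those outside the naming rule were chosen after their values were seen. LOC103440048 (chromosome 7, 21272732 to 21275848), named after EFR, the Arabidopsis receptor of a bacterial elongation factor, had 44.2 ± 14.0 CPM in resistant and 2.80 ± 1.12 CPM in susceptible leaves. LOC103413690 (chromosome 12, 983471 to 990570), named after the LRR kinase GSO2, had 111.7 ± 49.2 against 7.74 ± 4.51 CPM. LOC103450293 (chromosome 12, 19648745 to 19666071) had 2.56 ± 1.78 CPM in resistant leaves and no read in the susceptible ones. The opposite direction was led by the receptor-like protein 2 gene LOC103403641 at 0.928 ± 0.806 against 3.86 ± 2.63 CPM, the LRR kinase gene LOC103440348 at 0.344 ± 0.542 against 2.34 ± 1.39 CPM, where the groups did not overlap, and the wall-associated kinase gene LOC103400178 at 8.38 ± 5.54 against 24.9 ± 21.8 CPM. Each had an adjusted p of 0.833 over all genes in edgeR.

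In the set test (camera with Benjamini-Hochberg adjustment) the adjusted p was 3.24e-10 for LRR kinases, 1.37e-06 for receptor-like proteins and 6.80e-06 for the other receptor kinases. None of these held with an estimated correlation: adjusted p = 0.481 with an estimated correlation for LRR kinases, 0.472 for receptor-like proteins and 0.481 for the other kinases. The median level of the LRR kinase list, as log2 CPM relative to each gene's mean over the libraries, was 0.71 in Florina, 0.53 in Mahraji and 0.01 in Prima, against -0.86 in Vista Bella, -0.51 in Ambri and 0.33 in Red Delicious. The libraries with 13.7% and 6.21% heat shock counts were thus those lowest in these receptors. Without Vista Bella and Ambri the receptor-like proteins and LRR kinases kept their camera direction and the other kinases turned. The median log2 fold change over the NLR, receptor-like protein and receptor kinase lists together was then 0.31, against 0.54 with all libraries. No call is drawn from this fit, as its susceptible side has no replicate.

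**Figure D2:**
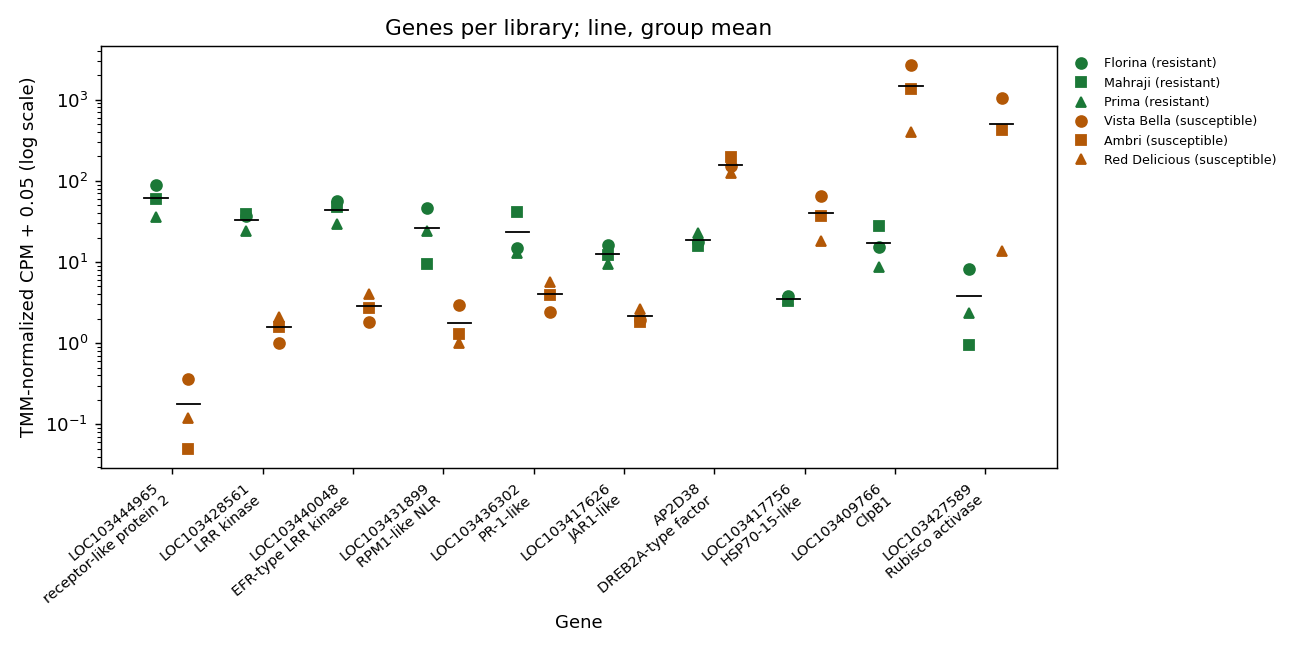
Points give TMM-normalized CPM plus 0.05 on a log axis for 10 genes in each of the 6 libraries (resistant cultivars green, susceptible orange), and horizontal lines give group means. LOC103444965 lay at 36.0 CPM or more in each resistant library and at 0.314 CPM or less in each susceptible one, and LOC103409766 ranged from 8.73 to 2662 CPM.

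NLR genes, which encode intracellular receptors of pathogen effectors, were also higher as a group in camera, with adjusted p = 5.06e-05 for all NLR genes, 8.96e-06 for the TIR type and 0.00941 for the coiled-coil type. There was no call at an estimated correlation: adjusted p = 0.481, 0.481 and 0.615 with an estimated correlation, in that order. Of 439 tested members 311 had a positive log2 fold change, with a median of 0.47. At an unadjusted p under 0.05 were 21 of these and 5 of those that were lower. The median was 0.59 over 188 TIR-type genes and 0.36 over 217 coiled-coil-type genes. In these lists 0 members passed either over all genes or adjusted over the list alone in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while DESeq2 called 10 NLR genes, all higher. LOC103431899 (chromosome 16, 1063909 to 1067106), named after RPM1, an Arabidopsis NLR for bacterial resistance, had 26.5 ± 18.4 CPM in resistant and 1.70 ± 1.04 CPM in susceptible leaves, a log2 fold change of 3.95 (SE 0.742). LOC103402474 (chromosome 15, 45095205 to 45095585), named after the tobacco virus resistance gene N, had 1.28 ± 0.747 CPM against 1 read in the 3 susceptible libraries together. LOC103432064 (chromosome 17, 1269475 to 1272774), also named after N, was at 0.495 ± 0.107 against 1.72 ± 0.552 CPM, the other way. The coiled-coil camera call was lost without Vista Bella (adjusted p = 0.155), without Ambri (0.167) and with library size alone as scaling (0.0807). Without both cultivars all NLR genes had 0.783, the TIR type 0.0916 and the coiled-coil type 0.171 with a reversed direction.

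How many NLR genes a leaf expressed was counted next. Of 1095 NLR genes in the annotation, 418 reached 1 CPM in Florina, 409 in Mahraji and 349 in Prima, against 286 in Vista Bella, 262 in Ambri and 360 in Red Delicious. The means were 392 ± 37.5 and 303 ± 51.1 (SD, n = 3), a difference of 89.3 genes with an exact two-sided permutation p = 0.2, where 3 against 3 libraries allow no p below 0.1. Red Delicious thus lay above Prima, and the difference was 32 with Red Delicious as the lone susceptible library. Over all genes, the number at 1 CPM or more was 28933 in Florina, 26247 in Mahraji and 25575 in Prima. It was 24909 in Vista Bella, 24868 in Ambri and 26379 in Red Delicious, again above Prima. The NLR counts used library totals without TMM factors and were not set against this general difference in detection.

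Further lists, of defence genes, MLO susceptibility genes and cell wall genes, were higher in resistant leaves as groups in camera with Benjamini-Hochberg adjustment, but not at an estimated correlation. Camera gave adjusted p = 5.14e-05 for pathogenesis-related proteins, 5.63e-05 for WRKY factors, 6.80e-06 for MLO, 0.0152 for salicylate and 0.0152 for cell wall genes, and in that order adjusted p = 0.481, 0.565, 0.472, 0.565 and 0.472 with an estimated correlation. Of 105 pathogenesis-related protein genes 79 had a positive log2 fold change (median 0.70), of 73 WRKY transcription factor genes 56 (median 0.52), and of 15 genes for MLO proteins, which powdery mildew needs to enter cells, 14 (median 1.16). Of 48 salicylate genes 31 were higher (median 0.26) and of 112 cell wall genes 76 (median 0.28). In edgeR 0 members of these lists passed adjusted over the list alone or over all genes, while DESeq2 called 3 pathogenesis-related genes, all higher, and 0 in the other lists. At an unadjusted p under 0.05 in edgeR were 11 pathogenesis-related genes that were higher and 1 that was lower, 5 WRKY and 5 MLO genes that were higher, 2 salicylate genes higher and 1 lower, and 8 cell wall genes higher and 3 lower. LOC103436302, a PR-1-like gene (chromosome 5, 23620776 to 23621317) of the secreted proteins that salicylate induces, had 23.2 ± 16.04 CPM in resistant and 3.95 ± 1.59 CPM in susceptible leaves. WRKY4 (chromosome 10, 19552984 to 19556116) had 24.98 ± 10.7 against 9.42 ± 3.12 CPM, and LOC103430003, an MLO-like protein 2 gene, 2.76 ± 1.5 against 0.526 ± 0.155 CPM. LOC103403007, a gene for a xyloglucan-remodelling enzyme, had 17.5 ± 24.6 against 0.961 ± 1.06 CPM, with 45.8 CPM in Mahraji alone. The opposite direction was led by another PR-1-like gene, LOC103404101, at 1.496 ± 0.789 against 7.94 ± 9.20 CPM, WRKY22 (LOC103407953) at 2.08 ± 1.30 against 4.29 ± 0.355 CPM, a TGA4-like factor gene of salicylate signalling (LOC103408449) at 0.407 ± 0.206 against 2.72 ± 2.64 CPM, the MLO-like protein 6 gene LOC103429291 at 6.81 ± 7.94 against 12.5 ± 6.70 CPM and an expansin-like B1 gene (LOC103436968) at 1.07 ± 1.37 against 11.8 ± 10.4 CPM. Each of these had an adjusted p of 0.8329 or higher over all genes in edgeR.

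The camera call of pathogenesis-related proteins was lost without Florina (adjusted p = 0.0863) and the WRKY call without Vista Bella (0.599) or without members named probable or putative (0.572). The salicylate call was lost without Florina (0.0665), Mahraji (0.0855) or Vista Bella (0.0690), and the cell wall call without Florina (0.0712), Mahraji (0.0690) or Red Delicious (0.0564), with no low-count filter (0.0720) and without probable or putative members (0.103). In median level per library some of these lists overlapped between the groups. Susceptible Red Delicious had the highest salicylate level (0.31), and its WRKY level (0.43) lay above Mahraji (0.35) and Prima (0.07). Its pathogenesis-related protein level (-0.12) lay above Prima (-0.24). For MLO and cell wall genes each resistant library lay above each susceptible one. With Red Delicious as the lone susceptible library, pathogenesis-related protein, cell wall and MLO genes kept their camera direction, while WRKY factors and salicylate genes turned. No call is drawn from this fit, as its susceptible side has no replicate.

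The jasmonate, ethylene, calcium and phenylpropanoid lists did not pass the set test. Camera adjusted p was 0.0583 for 71 jasmonate genes and for 209 calcium genes, 0.18 for 110 ethylene genes and 0.493 for 140 phenylpropanoid and flavonoid genes. Adjusted over the list alone, 1 jasmonate gene rose, LOC103417626 (chromosome 1, 163857 to 168740), of the JAR1 type that joins jasmonate to isoleucine to make the active hormone. It had 12.6 ± 3.49 against 2.09 ± 0.457 CPM (adjusted p = 0.0339 over the list alone by edgeR's quasi-likelihood test). LOC103456257, for the calmodulin-like calcium sensor CML44 (chromosome 15, 6572721 to 6573552), had 9.75 ± 2.30 against 0.199 ± 0.190 CPM. LOC103411651, for a TINY-like ethylene-responsive factor, had 4.87 ± 2.06 against 0.945 ± 0.647 CPM. Neither passed in edgeR over all genes or over the list alone, while DESeq2 called LOC103456257 (adjusted p = 6.10e-09). LOC103438446, a cinnamoyl-CoA reductase gene of lignin synthesis, had 2.51 ± 2.29 against 0.0419 ± 0.0726 CPM. LOC103406204, an anthocyanidin reductase gene of proanthocyanidin synthesis, had 28.9 ± 17.4 against 82.8 ± 19.5 CPM. The other lists had genes of the opposite direction too, none of which passed in edgeR: LOC103415553 of the jasmonate list, named after a lipoxygenase homology domain, at 0.232 ± 0.0744 against 1.18 ± 0.511 CPM, LOC103414730, a homolog of the enzyme that makes ethylene, at 1.64 ± 0.842 against 6.87 ± 2.40 CPM, and LOC103453354, for the calcium-binding protein CML48, at 18.5 ± 5.05 against 44.2 ± 6.19 CPM. The single tested gene for biphenyl phytoalexin synthesis, LOC103456250, had 23.4 CPM in Florina, 0.968 in Mahraji and 0.147 in Prima, against 2.52 in Vista Bella, 1.25 in Ambri and 0.137 in Red Delicious. The jasmonate list passed without Ambri (0.0363), with a filter of 1 CPM in at least 3 libraries (0.0269) and without probable or putative members (0.0387). Calcium passed with that filter (0.0266) and without Florina (0.0172), Prima (0.0148) or Red Delicious (0.0119), and ethylene without Prima (0.0295) or Red Delicious (0.0344). These are camera values at the preset correlation. With an estimated correlation over all libraries, camera gave adjusted p = 0.565 for jasmonate, 0.6605 for calcium and 0.6605 for ethylene.

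Ribosomal protein, oxidative and photosynthesis genes were lower in resistant leaves as groups in camera, with adjusted p = 2.01e-05, 0.00979 and 0.0138, and adjusted p = 0.660, 0.472 and 0.703 with an estimated correlation. None of these lists parted the cultivars by group. In photosynthesis genes resistant Prima had the highest level of the 6 libraries (0.69, with 16.8% of its counts) and resistant Florina the lowest (-0.53). In ribosomal protein genes Prima (0.27) lay above susceptible Ambri (0.23) and Red Delicious (-0.20). In oxidative genes Florina (0.07) lay above Red Delicious (-0.02). Of 511 ribosomal protein genes 411 had a negative log2 fold change (median -0.28), of 169 peroxidase, oxidase and detoxification genes 100 (median -0.16), and of 116 photosynthesis genes 66 (median -0.07). In edgeR 0 members of these lists passed adjusted over the list alone or over all genes, and at an unadjusted p under 0.05 were 1 higher and 6 lower, 3 higher and 22 lower, and 1 higher and 2 lower genes in that order. DESeq2 called 1 ribosomal protein gene and 8 oxidative genes, all lower, and 1 photosynthesis gene in each direction. LOC103427589 (chromosome 4, 2898798 to 2902346), a Rubisco activase gene, whose product frees the carbon-fixing enzyme of inhibitors, had 3.79 ± 3.88 CPM in resistant leaves and 1062 CPM in Vista Bella, 418.5 in Ambri and 13.5 in Red Delicious, and was the photosynthesis gene that DESeq2 called lower (adjusted p = 1.57e-06). The one it called higher was LOC103415605 (chromosome 15, 2479897 to 2481785), for photosystem I chlorophyll-binding protein 5, with 50.2 ± 27.2 against 9.48 ± 2.56 CPM (DESeq2 adjusted p = 0.00611). LOC103435649, a glutathione S-transferase gene (chromosome 5, 13673179 to 13674536), had 37.6 ± 18.02 against 331 ± 182 CPM (DESeq2 adjusted p = 0.000132), and LOC103412392, for ribosomal protein L44, 12.1 ± 1.65 against 33.5 ± 6.11 CPM. The ribosomal call was lost without Mahraji (0.209) or Vista Bella (0.0690), the oxidative call without Mahraji (0.155) or Vista Bella (0.0690), with no low-count filter (0.201) and without probable or putative members (0.113), and the photosynthesis call without Florina (0.708), Mahraji (0.279) or Ambri (0.0558). With Red Delicious as the lone susceptible library none of these lists passed (0.487 with a reversed direction, 0.605 and 0.0916).

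Markers of other leaf cell types and of leaf age did not separate the groups in the set test. The 7 guard cell genes had a median log2 fold change of 0.575, with 5 higher, near the LRR kinase median of 0.585. A missing call on so short a list does not show that the share of guard cells was alike. Camera adjusted p was 0.836 for 50 cuticle and epidermis genes, 0.323 for 40 vascular genes, 0.311 for 7 guard cell genes, 0.514 for 27 senescence genes and 0.625 for the 121 genes of the cell division list. By its search term that list also took up cyclin-dependent kinases and calcyclin-binding proteins, and without them 92 genes were left (adjusted p = 0.911, camera). Adjusted over the list alone by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, LOC103419804, a cyclin-B3-1 gene (chromosome 5, 1594504 to 1595794), rose, with 9.07 ± 5.91 CPM in resistant and 0.07 ± 0.0738 CPM in susceptible leaves. LOC103435000 fell, at 8.53 ± 1.90 against 188 ± 157 CPM. It encodes a calcyclin-binding protein and not a cyclin. LOC103441005, for a vacuolar processing enzyme, a protease of ageing and dying cells, fell from 62.1 ± 17.6 CPM in susceptible to 20.4 ± 1.58 CPM in resistant leaves (adjusted p = 0.0319 over the list alone by edgeR). The senescence list passed camera at the preset correlation without Mahraji (0.0489), lower in resistant leaves. Its direction was the same with Red Delicious as the lone susceptible library. With an estimated correlation over all libraries, camera gave adjusted p = 0.739 for senescence and 0.774 for clock genes. Clock genes had an adjusted p = 0.635, with a positive median (0.18) and mean (0.31) log2 fold change and a negative camera direction, and an adjusted p = 0.0300 without Mahraji. LOC103417671, of the LHY type of morning clock factor, had 154 CPM in Mahraji and 0.189 CPM in Florina, with 4.56 to 7.05 CPM in the other libraries.

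**Figure D3:**
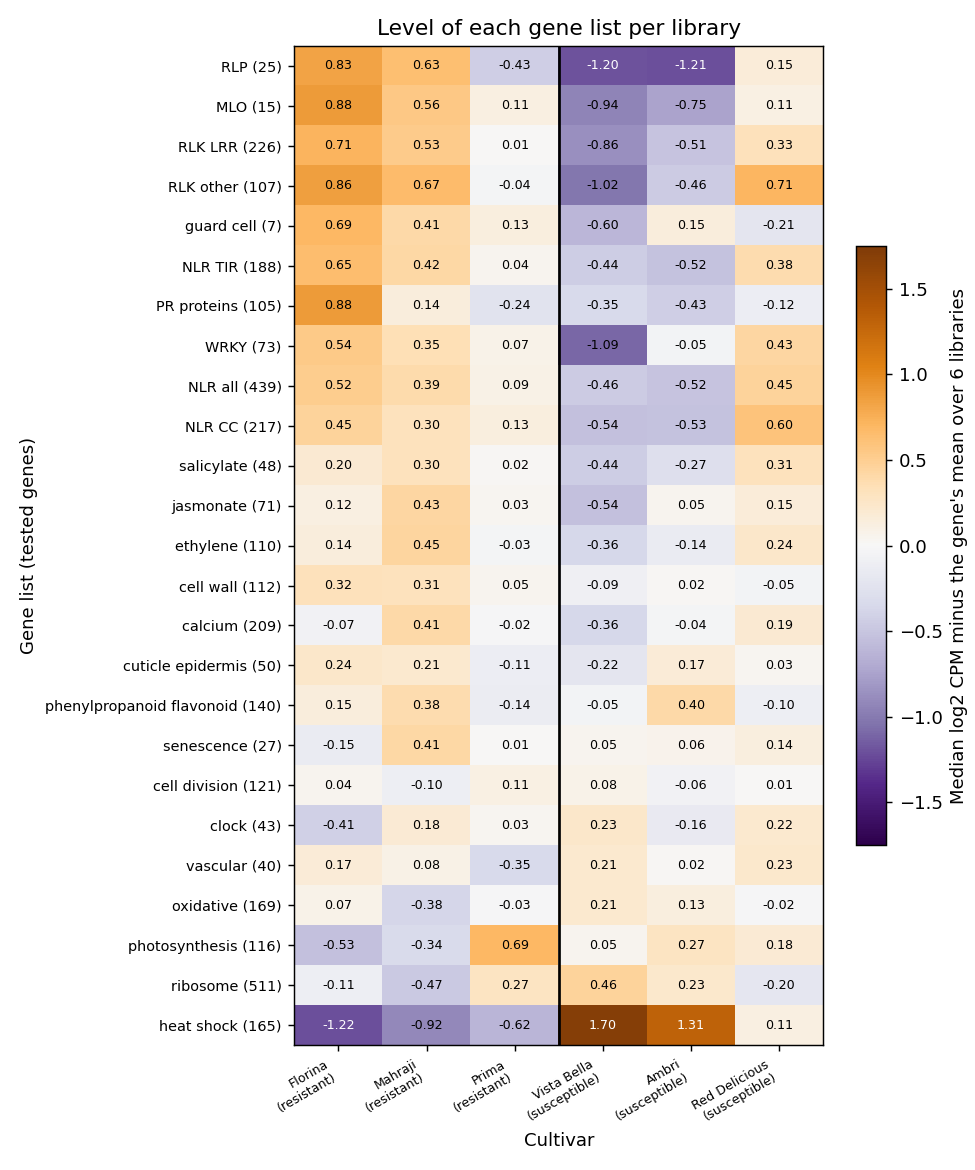
Colours and printed values give, for 25 gene lists (rows, with the number of tested genes) and 6 libraries (columns), the median over the list of log2 CPM minus each gene's mean over the libraries. Heat shock genes were at 1.70 in Vista Bella and 1.31 in Ambri and at -0.62 or lower in the resistant libraries, and Red Delicious had 0.45 for all NLR genes, between 0.39 in Mahraji and 0.52 in Florina.

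A gene of the Golden Delicious reference that is missing from the susceptible cultivars would show as reads in one group and none in the other. A gene absent from that reference, as one introgressed from a wild apple can be, is not covered. By the fixed rule 8 genes were detected in the resistant cultivars alone and 3 in the susceptible ones alone, and no NLR, receptor-like protein or receptor-like kinase gene was among them. The receptor-like protein gene LOC103450293 missed the rule narrowly, with 36 reads in Florina, 60 in Mahraji and 13 in Prima, just under 1 CPM, and 0 in the susceptible libraries. At a minimum of 0.5 CPM 25 genes were detected in one group alone, 3 of them receptor genes, all in the resistant cultivars. LOC103431638 (chromosome 3, 28638613 to 28639204), a protein-coding gene of unknown function, had 5.08 ± 0.776 CPM in resistant leaves and 0 reads in susceptible ones. That is at least 74.6-fold higher at a floor of 3 counts over the group. LOC103406975 on chromosome 2 and LOC108175135, a long noncoding RNA gene on chromosome 2, likewise had 0 reads in all 3 susceptible libraries. These genes were chosen after their values were seen. All 11 genes are uncharacterized, noncoding or a pseudogene in the annotation. The count moved with single libraries, being 35 without Florina, 26 without Mahraji, 41 without Prima, 36 without Vista Bella, 21 without Ambri and 73 without Red Delicious.

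How far apart cultivars lay within and between the groups was measured over 500 variable genes. The mean distance was 99.4 between and 86.5 within groups, a difference of 12.95, with an exact one-sided permutation p = 0.1, the smallest that 3 against 3 libraries allow. The difference was 5.26 without Vista Bella, 5.21 without Ambri and 30.7 without Red Delicious. On the first principal component, with 33.4% of the variance, Vista Bella and Ambri lay apart from the other 4 libraries. Genes at 1 CPM or more in a single cultivar and under 0.1 CPM in the other 5 numbered 92 in Florina, 51 in Mahraji, 49 in Prima, 41 in Vista Bella, 37 in Ambri and 20 in Red Delicious. With 1 library per cultivar these counts have no replicate check.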

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

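The fits without Vista Bella and Ambri, with the heat shock score as a covariate and without list members caught by accident were chosen after seeing the data. The count of genes past an adjusted p of 0.05 in edgeR was 0 under every scaling, filter and threshold tried, without each cultivar in turn (lowest to highest 0 to 0) and in limma-voom, while DESeq2 called 380; the cause was not tested. Counts at an unadjusted p under 0.05 ran from 1108 to 3135 without one cultivar. Heat shock genes kept their direction and call without each cultivar and under every scaling and filter. Lists past camera numbered 13 to 17 under other scalings, filters and memberships and 10 to 17 without one cultivar, but 0 with an estimated correlation and 0 with fry, 5 without Vista Bella and Ambri, and 8 with the heat shock score as a covariate. The direction of a list past camera did not turn without any one cultivar.

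Turned directions are given with their camera adjusted p. Cuticle genes turned with library size alone (0.697) and cell division genes with no low-count filter (0.828). Without one cultivar some lists that had missed the threshold turned, with ranges of 0.0295 to 0.977 for ethylene, 0.358 to 0.977 for cuticle, 0.347 to 0.977 for cell division, 0.0489 to 0.927 for senescence and 0.0300 to 0.909 for clock genes. Without Vista Bella and Ambri, which leaves 1 susceptible library assumed to vary like the others, coiled-coil NLR (0.171), other receptor kinases (0.56), WRKY (0.316), salicylate (0.945), jasmonate (0.636), ethylene (0.916), calcium (0.465) and ribosomal protein genes (0.487) turned. The heat shock score had a correlation of -0.913 with the group over the 6 libraries. A fit with both terms can hardly tell them apart, so its turned directions are no evidence of a change in these lists. With the heat shock score as a covariate, turned lists that passed at the preset correlation of 0.01 were all NLR (0.00539), coiled-coil NLR (5.21e-06), LRR kinases (1.48e-05), other receptor kinases (5.21e-06), WRKY (4.23e-06), salicylate (0.00767) and ribosomal proteins (0.00138). Those that did not pass were TIR-type NLR (0.209), receptor-like proteins (0.952), MLO (0.668), jasmonate (0.186), ethylene (0.123), calcium (0.137), oxidative (0.788) and cuticle genes (0.952), and heat shock genes (0.788), whose own level the covariate removes.

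Among named genes the log2 fold change turned in 14 fits. It ran from -1.24 to 3.53 for LOC103456250, from -0.64 to 0.0917 for LOC103412399 and from -0.98 to 3.81 for LOC103417671 without one cultivar, was -0.11 for LOC103417671 in limma-voom and 0.16 for LOC103403641 without Vista Bella and Ambri. With the covariate it was 1.33 for LOC103447172, 2.504 for LOC103403641, 2.61 for LOC103404101, -0.80 for LOC103420621, 1.18 for LOC103408449, 0.93 for LOC103442204, -0.0452 for LOC103421485, 3.003 for LOC103427589 and -0.35 for LOC103420228. None of these genes passed over all genes in edgeR in these fits, and DESeq2 called LOC103427589 with an adjusted p of 1.57e-06 and a log2 fold change of -7.08.

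Genes detected in one group alone numbered 5 at 2 CPM against 0 reads, 25 at 0.5 CPM, 21 to 73 without one cultivar and 127 without Vista Bella and Ambri, since fewer libraries must then meet the rule. Receptor genes among them numbered 0 in the first of these settings, 3 in the second, 0 to 6 without one cultivar and 10 in the last. Genes of a single cultivar numbered 67 at 2 CPM against 0 reads. The difference in expressed NLR genes stayed positive, from 69 to 118 without one cultivar, and the difference in distances ran from 5.21 to 30.7. Thinned to the shallowest library, the difference in expressed NLR genes was 86.7 and 12 genes were detected in one group alone. No paired analysis was possible because the replicate numbers were assigned here in accession order, not given by the labels, and each cultivar has 1 library.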

Other observations

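Chosen after the result was seen were the count of genes past the threshold in other splits, the tests of harvest conditions, of a few abundant genes and of depth, and the fits without Vista Bella and Ambri and with the heat shock score as a covariate. The comparison of neighbouring genes at equal gene numbers was added after the ratios in other splits were seen. The tests of abundant genes and of depth replaced planned ones, without the 20 most abundant genes and with thinned libraries, which moved too little to decide. A later count of receptor genes with at least 10 reads in thinned libraries was dropped too, since the deeper libraries were the susceptible ones and fixed its direction. Small heat shock proteins hold unfolding proteins in solution. LOC103436955 (chromosome 6, 5768371 to 5769505), a 17.1 kDa class II small heat shock protein gene, had 11320 CPM in Vista Bella, 4988 in Ambri and 497 in Red Delicious, against 42.9 to 80.4 CPM in the resistant libraries. LOC103452075 (chromosome 13, 7362390 to 7363557), for a chloroplast small heat shock protein, had 7611, 4084 and 431 CPM in the same order, against 29.9 to 75.9 CPM. Both genes were chosen after their values were seen.

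Several genes that were higher in all resistant libraries are neighbours on the chromosome, all chosen after their values were seen. On chromosome 17, the TIR-type NLR genes LOC103404849 (log2 fold change 3.25), LOC108169933 (3.19) and LOC103404850 (5.56) lie between 4772697 and 4787122. On chromosome 5, the PR-1-like genes LOC103436328 (2.26) and LOC103436302 (2.55) start at 23577724 and 23620776. On chromosome 7, the receptor kinase genes LOC103428560 (3.40) and LOC103428561 (4.44) start at 73315 and 107988. Among 128 genes higher in all resistant libraries at an unadjusted p under 0.01, 13 pairs with different product names lay within 50 kb, against 4.42 in random draws (permutation p = 8e-04 over 9999 draws). For 233 genes lower in all resistant libraries the numbers were 16 and 14.1 (permutation p = 0.343). The rule on product names left related neighbours in, among them the NLR and receptor kinase genes above. Gene families were thus not taken out, and reads shared among relatives were not tested. The hypothesis that such runs go with resistance was set against other splits of the 6 libraries: the ratio of seen to random pairs was 3.005 in the real split, and 6 of the 18 arms of the other splits reached it, the highest 4.87. The 6 arms that did held fewer genes, so the test was repeated with 128 genes in each arm: the real arm had 13 pairs, and 3 of the 18 other arms had as many (median 8.5, highest 14). The division by scab resistance did not stand apart from the other divisions in this test, and linked differences between cultivars in general may account for the closeness.

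Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. The count of genes past the threshold in edgeR was 0 in the real split and the highest other was 0, so all 10 splits reach it by construction and the comparison says nothing about chance. Lists past camera were as many in 4 of the 10 splits (real 15, highest other 18), and genes detected in one group alone in 5 of the 10 (real 11, highest other 21). The heat shock median was as far from 0 in 1 of the 10, the real one (1.89, highest other 1.53), while the photosynthesis median was as far from 0 in all 10 (0.0683, highest other 0.615). Counted with the real split, receptor-like proteins reached their median in 4 of the 10 (0.82, highest other 1.42). Pathogenesis-related proteins did so in 4, the other receptor kinases in 3, ribosomal proteins in 5 and oxidative genes in 6. All NLR genes, LRR kinases (0.58, highest other 0.99) and WRKY factors did so in 2 each. MLO did so in the real split alone (1.164, highest other 1.157). The split of Florina, Mahraji and Red Delicious from Prima, Vista Bella and Ambri gave 2809 genes at an unadjusted p under 0.05 against 1689 and a receptor median of 0.80 against 0.54, which points to a structure of the libraries other than the resistance label.

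The first pattern is the heat shock list, lower in each resistant library than in each susceptible one. With library size alone the median log2 fold change of all genes was 0.28, the opposite sign to the list's -1.66. TMM factors moved the median of all genes by 0.247 and kept 1.14 of the list's median. Against a few abundant genes as the whole cause stands that this shift was far smaller than the list's median. Depth as the whole cause is argued against by size too. The log2 ratio of mean totals was -0.28, and the list's median in unscaled counts was -1.98. Scaling by library size moved the median of all genes by 0.284 and kept 0.838 of the list's median. Shifts of these sizes fixed both kept shares in advance, so the shares add no evidence of their own. Open is whether leaves were taken at different temperatures, hours or delays: the widest range of the list's level within a group was 0.812 of the gap between group means, and with 1 library per cultivar harvest and cultivar cannot be told apart. A lasting difference between the cultivars, which the design names, stays open too and was not tested.

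The second pattern is the higher level of NLR, receptor-like protein and receptor kinase genes in resistant leaves. Depth is argued against by unscaled counts: the resistant libraries were the shallower ones, with a log2 ratio of mean totals of -0.28, which would lower these genes, yet their unscaled median log2 fold change was 0.51 (0.31 to 1.01 without one cultivar). The heat shock state of the libraries is a candidate explanation: with the heat shock score as a covariate the receptor median went from 0.54 to -0.66, a kept share of -1.23, though the score separates the groups, 2.89 to 3.12 against 4.33 to 6.01, and 3 residual degrees of freedom remain. Within the susceptible group Vista Bella had the highest score (6.01) and the lowest LRR kinase level (-0.86), but within the resistant group Prima had both the lowest score (2.89) and the lowest LRR kinase level (0.01). A lower share of mesophyll in resistant leaves stays open, as the lowest of the cuticle, vascular and guard cell medians was -0.0737 (bootstrap SE 0.157) relative to all genes, and scab resistance itself was not separable from these.

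The third pattern is LOC103444965, the receptor-like protein 2 gene with 6 reads in the 3 susceptible libraries together and 2720 in the resistant ones. If reads of a susceptible allele had been counted on a paralog, the 50 other genes of that product name would hold the missing reads. Their summed CPM was lower in susceptible libraries by 13.3 on average (difference -13.3). An allele expressed at the resistant level would need 61.9 CPM there. The treatment of reads that match several loci is not given, and if such reads were dropped the sum could not rise. Its level in Red Delicious, 0.0687 CPM, was as near to 0 as in Vista Bella and Ambri, although Red Delicious had receptor list levels like those of the resistant libraries. An allele of the susceptible cultivars too diverged to align, reads dropped for matching several loci, a deletion or silence of the gene remain open. Also open is whether reads of a gene that resistant cultivars carry and Golden Delicious lacks were counted on this gene. These explanations were not tested, since the reads were not analysed here. The gene was not compared with Vf sequences. The value of -13.3 bears on reads counted on paralogs of that product name alone.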
